A study of mouse gut metagenome with 17 samples.

How the data were processed

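Cecal contents of 17 mice were profiled by amplicon sequencing. Per the labels' protocols, DNA was isolated from 50 mg of contents of each mouse, V4 amplicons of the bacterial 16S gene were made in triplicate reactions and pooled, and sequencing was done on an Illumina MiSeq with paired reads of 150 bp. The series is typed as expression profiling, but the protocols describe amplicons of genomic DNA and the values were treated as such. The authors deposited read counts per sequence variant (389 rows, named for the deblur denoiser), per operational taxonomic unit (342 rows) and per taxon (52 rows), exported from BIOM files per the file headers. The deposited taxonomy gives each variant a name of 7 ranks and a confidence as a fraction, with a lowest value of 0.701 and a median of 0.998. The versions, the classifier, the reference database, the trimming, the chimera step and the clustering tool are not given in the sources used here. The deposited counts are whole reads without normalization. Totals of the 3 tables were equal in every sample, and the taxon table equalled the variants summed by taxonomy in every cell. A total of 382 variants and 337 units had a read in these samples. Names follow the deposited taxonomy: "without a genus name" is an empty rank of the reference, and "called to family only" means that the assignment stopped there. A genus given alone stands for its taxon without a species name, and species and genus-only calls are separate taxa.

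Groups came from the sample titles. Batch, cage and sex were not in the labels. No pair of samples within a group agreed within sampling noise. The total was 798693 reads, 24034 to 85504 per sample, so that 3 reads were 0.00351% to 0.0125% of a sample. Ages were compared between different mice.

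Taxa and variants with at least 5 reads in at least 3 samples were tested (46 taxa with 99.1% of reads and 306 variants with 98.3%). The main test was edgeR 4.0.16 in R 4.3.3, with estimated dispersions, glmQLFit and glmQLFTest, all 4 groups in 1 fit, library totals without a composition factor, and Benjamini-Hochberg adjustment at 0.05. A fold change is therefore one of the share of reads. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic. It thus restates the test and is not a separate estimate of precision. Every adjusted p of a taxon or variant comes from this test unless another is named. The same fit tested the treatment by age interaction. Where a group had no read, the fold is a lower bound against 3 reads of the group's pooled total, and with 1 to 3 reads it is the ratio of pooled reads with an exact 95% counting interval. Other folds are ratios of mean shares. PCR reads are not independent molecules.

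Observed variants were averaged over 100 draws of 24034 reads. The Shannon index used all reads. Differences of group means were tested by exact two-sided permutation over all 126 relabellings of 4 against 5 mice or 70 of 4 against 4, adjusted over the 4 comparisons, with smallest p of 0.00794 and 0.0286. The interaction was tested with 100000 permutations. A permutational test of R2 was run over the same relabellings on Bray-Curtis distances of variants. Phyla with a mean share of at least 0.1% in a group and 13 fixed taxon groups, of which 11 had a member, were tested on summed shares. The list of signals from outside the resident flora (plant plastids, mitochondria and reagent contaminants) and that of Candidatus Arthromitus had no member. The former named Pseudomonas but not Pseudomonadaceae called to family only. That taxon had 4 reads in controls and 11 in ampicillin mice at 6 weeks, and 2 and 0 at the endpoint. An empty list thus does not exclude reagent contaminants. The Erysipelotrichales list also held Turicibacter, which the deposited taxonomy places in another order, Turicibacterales. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.

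Tests, groups, taxon lists, alternatives and the rule for named taxa were fixed before the data were examined. The rule takes, per comparison, up to 12 higher and 12 lower taxa with the largest fold among those past the threshold, the 5 most abundant taxa, every list member with at least 1% of reads in a group compared, the 3 variants per direction with the largest fold, and the 5 smallest interaction p. Taxa named outside it were chosen after their values were seen. Alternatives were TMMwsp factors, DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log ratios with a pseudocount of 0.5 reads, no filter, a filter of 50 reads in 4 samples, a robust fit, a fit of only the groups compared, the operational taxonomic units, other diversity measures and distances, a log2 scale with 0.01%, the replicate number as a block, and leaving out each mouse. As alternatives chosen after seeing the data, reads outside Bacteroidetes and reads of Clostridiales served as library totals.

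The edgeR step was tested on simulated counts for the 6-week comparison. At a dispersion of 0.2 it recovered 95% of 4-fold and 100% of 16-fold changes among 46 taxa, and 90.2% and 97.2% among 306 variants. At the dispersions estimated from the data it recovered 5% and 46.7% among taxa and 0% and 9% among variants. False calls were at most 1.5%. These simulations kept library totals fixed, gave each taxon or variant the same spread in all groups and removed none from a group. They therefore do not give the rate of false calls where many reads are displaced. The exact tests of observed variants and of R2 gave 4.2% and 5.6% of 500 unchanged simulations a p under the threshold. Those groups were drawn alike at equal depth, so these rates follow from the permutation and do not cover unequal spread.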

Results

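The bacterial community of the cecum, the pouch at the start of the large intestine, was profiled in 17 mice by sequencing the V4 region of the bacterial 16S rRNA gene. The mice were C57BL6 animals with a knockout of exon 16, used as a model of hemophilia A, the bleeding disorder caused by lack of coagulation factor VIII. Ampicillin, a beta-lactam antibiotic, was given by gavage from 3 weeks of age at 50 mg/kg every 12 h for 7 days. There were 4 control mice and 5 ampicillin mice at 6 weeks of age, and 4 control mice and 4 ampicillin mice at the study endpoint, which the design text places at 10 weeks and the sample labels call only endpoint. Each sample came from 1 mouse, and different mice were sampled at each age, so ages were compared between animals. Read totals ranged from 24034 to 85504 per sample with a median of 43640. They ranged from 25174 to 75766 in controls at 6 weeks, from 43372 to 85504 in ampicillin mice at 6 weeks, from 29484 to 53889 in controls at the endpoint and from 24034 to 52558 in ampicillin mice at the endpoint. A taxon without a read in a group could still hold up to 3 reads of the group's pooled total, which is 0.00102% to 0.00203% of reads. Such floors and all counting intervals cover counting error only. All values are shares of reads, since bacterial load was not measured. Mice were taken as independent, but cages were not in the labels, and p-values may be too small if mice of a group shared cages.

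The first comparison asked whether the cecal community of ampicillin mice differed from that of controls at 6 weeks. Firmicutes made up 54.3% ± 9.48 of reads in controls (SD, n = 4) and 92.5% ± 10.2 in ampicillin mice (SD, n = 5). Bacteroidetes made up 39.4% ± 9.96 and 7.45% ± 10.2 of reads, the latter from ampicillin replicates 1 and 2 (mean 4.36% without the one and 4.96% without the other). Deferribacteres, at 3.24% ± 0.959 in controls, Actinobacteria, at 0.242% ± 0.0311, and Cyanobacteria, at 0.217% ± 0.109, had no read in the 5 ampicillin mice. Proteobacteria made up 2.56% ± 0.205 in controls and 0.0599% ± 0.0907 in ampicillin mice (0.0198% without replicate 4). All 6 phyla passed the exact permutation test (two-sided, adjusted p = 0.00794, the smallest p that 4 mice against 5 can give), with 1 higher and 5 lower. Firmicutes took at least 80.2% of reads in each of the 5 ampicillin mice and at most 66.4% in each of the 4 controls.

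**Figure D1:**
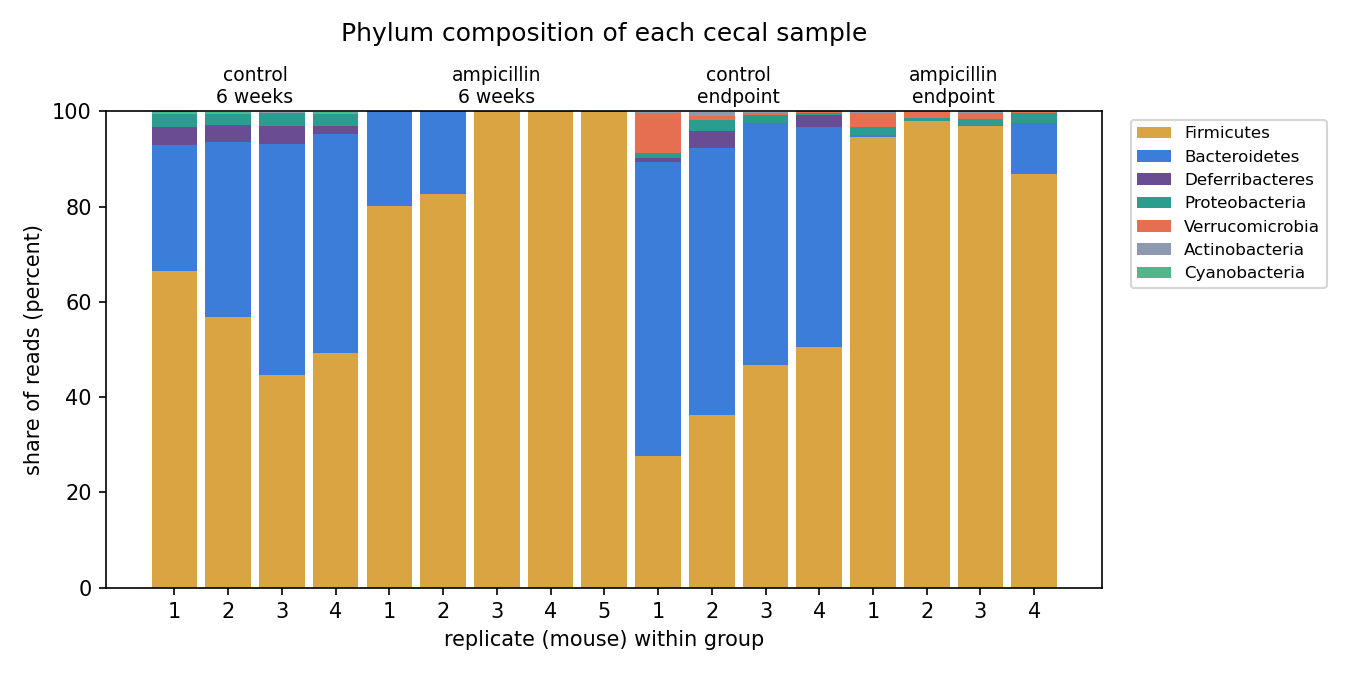
Stacked bars give the share of reads in percent of 7 phyla in each of the 17 mice, grouped by treatment and age, with replicate numbers on the horizontal axis. Bacteroidetes took 26.5% to 48.5% of reads in the 4 controls at 6 weeks and at most 19.8% in the 5 ampicillin mice of that age.

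Among the taxa of the deposited taxonomy, 33 of 46 tested changed at 6 weeks, 10 higher and 23 lower in ampicillin mice. The family S24-7, the Muribaculaceae of newer taxonomies and a main Bacteroidales family of the mouse gut, fell from 28.9% ± 13.6 of reads to 0.00767% ± 0.00397 (log2 fold change -11.83 ± 1.28 SE, adjusted p = 2.39e-06), with at least 9.95% in each control and at most 0.0117% in each ampicillin mouse. Rikenellaceae without a genus name fell from 4.68% ± 3.77 to no read, at least 4580-fold lower (2830-fold without control replicate 1, at 10.1%). Bacteroides acidifaciens, Prevotella without a species name and AF12 made up 1.43% ± 0.745, 1.21% ± 1.15 and 1.00% ± 0.359 of reads in controls and had no read in ampicillin mice, at least 1400-fold, 1180-fold and 980-fold lower, the second 630-fold without control replicate 3. Of the 9 Bacteroidales members tested, 7 were lower, 0 higher and 2 not past the threshold. Bacteroides without a species name was 1 of the latter, at 1.93% ± 0.993 in controls and 7.44% ± 10.2 in ampicillin mice (adjusted p = 0.492). Its share was 19.8% and 17.4% in ampicillin replicates 1 and 2 and at most 0.00922% in the other 3 mice.

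Losses at 6 weeks reached beyond Bacteroidales. Mucispirillum schaedleri, an inhabitant of the mucus layer, was at least 3170-fold lower. Sutterella, at 1.31% ± 0.305 of control reads, was at least 1280-fold lower, and Bilophila, which respires sulfite released from taurine, was at least 895-fold lower from 0.916% ± 0.38. Of the 6 Proteobacteria members tested, 5 were lower and 1, Enterobacteriaceae, was higher at 0.0559% ± 0.0904 of reads in ampicillin mice and no read in controls. Ampicillin replicate 4 held 0.216% of Enterobacteriaceae, the mean without it was 0.016% (adjusted p = 0.0105), and the call ended with the replicate block (adjusted p = 0.0544). Lactobacillus without a species name, Butyricicoccus pullicaecorum, Adlercreutzia and Allobaculum lay between 0.219% and 0.255% of control reads and had no read in ampicillin mice, at least 249-fold, 244-fold, 234-fold and 214-fold lower. Without control replicate 2 the bound of Lactobacillus was 88.1-fold, and without control replicate 4 that of Allobaculum 53.8-fold. The calls for Lactobacillus and Allobaculum ended on centred log ratios, with adjusted p = 0.385 and 0.293 by limma. The separate taxon of Lactobacillus called to genus only, named after its values were seen, kept 0.481% and 0.243% of reads in ampicillin replicates 1 and 2.

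The taxa that took a larger share at 6 weeks were mostly Clostridiales, the order of most anaerobic spore formers of the gut. Lachnospiraceae without a genus name rose from 4.08% ± 0.938 to 20.2% ± 2.91 of reads (log2 fold change 2.31 ± 0.42 SE, adjusted p = 0.000178). Clostridiales without a family name rose from 7.62% ± 1.54 to 24.3% ± 4.45 (1.67 ± 0.247 SE, adjusted p = 2.27e-05) and Oscillospira from 4.39% ± 0.466 to 13.3% ± 3.39 (1.60 ± 0.313 SE, adjusted p = 0.000341). Coprococcus, a genus with butyrate producers, rose 10.4-fold to 4.45% ± 0.639, Lachnospiraceae called to family only 3.97-fold to 11.1% ± 4.59, and [Ruminococcus] gnavus, a mucin degrader, 3.67-fold to 2.14% ± 1.39. Clostridium methylpentosum rose 4.91-fold to 1.49% ± 0.204, a call that ended without any 1 of the 4 controls (adjusted p = 0.0523 to 0.0841) or without ampicillin replicate 3 (adjusted p = 0.05). Clostridiales called to order only took 31.3% ± 6.82 of reads in controls and 12.8% ± 10.6 in ampicillin mice (adjusted p = 0.0733), and Ruminococcus 1.03% ± 0.191 and 1.05% ± 0.241 (adjusted p = 0.975). With reads outside Bacteroidetes as the total, chosen after seeing the data, the order-only taxon was lower (-1.98 ± 0.57 SE, adjusted p = 0.00588). Of the 18 Clostridiales members tested, 7 were higher, 4 lower and 7 not past the threshold.

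Scaling set the balance of higher and lower calls at 6 weeks. The median log2 fold change over the taxa tested was -4.04 on shares, -4.95 with TMMwsp factors, -2.85 with DESeq2 and 0.13 on centred log ratios. TMMwsp gave 1 higher and 26 lower calls, DESeq2 12 and 21, and limma on centred log ratios 17 and 14. Among sequence variants TMMwsp gave 11 higher and 176 lower calls. None of the 7 Clostridiales taxa named as higher passed with TMMwsp factors, although their log2 fold changes stayed above 0. Staphylococcus and Turicibacter, at no read in controls and 0.032% ± 0.0469 and 0.0167% ± 0.0355 in ampicillin mice, passed with adjusted p = 0.0248. The means were 0.0117% without ampicillin replicate 3 and 0.000877% without ampicillin replicate 1. Both calls ended with TMMwsp factors (adjusted p = 0.0501 and 0.0652), with only the groups compared in the fit (0.0583 and 0.111) and without control replicate 3 (adjusted p = 0.053 and 0.0544), the first also without ampicillin replicate 3 (adjusted p = 0.0507) and the second without ampicillin replicate 1 (adjusted p = 0.157).

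The summed shares of 11 taxon groups fixed beforehand were tested at 6 weeks, and 8 changed, 5 higher and 3 lower. The lists overlap, so these are not counts of separate changes. Lachnospiraceae, Ruminococcaceae, the butyrate-producing genera and the clostridial list described below lie within Clostridiales. Muribaculaceae lie within Bacteroidales, which held the same reads as the phylum Bacteroidetes in every mouse. Lachnospiraceae rose from 7.96% ± 2.1 to 38.6% ± 6.12 of reads, Ruminococcaceae from 6.57% ± 0.614 to 16.6% ± 4.37, Clostridiales from 53.7% ± 9.61 to 92.3% ± 10.4, and the butyrate-producing genera from 5.07% ± 0.55 to 17.8% ± 3.01. Most of the butyrate-producing sum was Oscillospira (4.39% and 13.3%). Of its other members, Coprococcus rose from 0.43% to 4.45% and Butyricicoccus pullicaecorum fell from 0.25% to no read. The list of clostridial genera drawn up for bile acid 7-alpha-dehydroxylation and related species rose from 0.947% ± 0.206 to 4.34% ± 2.14. It held Clostridium colinum, Clostridium methylpentosum, Dorea, [Ruminococcus] gnavus and Blautia producta, none of them a species established for that activity, and most of the sum was [Ruminococcus] gnavus (2.14%) and Clostridium methylpentosum (1.49%). Bacteroidales, Muribaculaceae and Proteobacteria were lower. The exact adjusted p of these 8 groups was 0.0146 to 0.0327 (two-sided permutation test). Facultative anaerobe families (0.389% ± 0.373, or 0.222% without control replicate 2, and 0.233% ± 0.163, exact adjusted p = 0.498), mucus-associated genera (6.60% ± 1.62 and 7.44% ± 10.2, or 4.35% and 4.95% without ampicillin replicate 1 or 2, exact adjusted p = 0.905) and Erysipelotrichales (0.235% ± 0.322, or 0.0759% without control replicate 4, and 0.0414% ± 0.0572, or 0.0231% without ampicillin replicate 1, exact adjusted p = 0.107) did not pass. Among members, 4 of 6 Lachnospiraceae were higher and 0 lower, and 2 of 6 Ruminococcaceae were higher and 2 lower. Of the 3 butyrate producers, 2 were higher and 1 lower. Of the 4 facultative anaerobes, 2 were higher and 1 lower, of the 4 mucus-associated taxa 2 were lower, of the 4 Erysipelotrichales 1 (Turicibacter) was higher and 2 lower, and of the 4 taxa of the listed clostridial genera 2 were higher. With TMMwsp factors 0 of the Clostridiales, and so of the Lachnospiraceae, Ruminococcaceae, butyrate producers and listed clostridial taxa, were higher and 6 Clostridiales lower, with DESeq2 9 and 4 Clostridiales and by limma on centred log ratios 10 and 1. Without any 1 control or without ampicillin replicate 3, 1 Ruminococcaceae member and 1 listed clostridial member were higher, without control or ampicillin replicate 3 1 facultative anaerobe, and without control replicate 3 or ampicillin replicate 1 0 Erysipelotrichales. Adjusted over the list alone, the counts of higher and lower members were the same in all 11 lists, although 0 listed clostridial members were higher without control replicate 3 or 4 or ampicillin replicate 3, and 1 without control replicate 1 or 2 or ampicillin replicate 4 or 5.

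Observed sequence variants at equal depth numbered 235 ± 7.47 in controls and 75.5 ± 10.3 in ampicillin mice at 6 weeks (SD, n = 4 and 5, exact permutation p = 0.00794, adjusted p = 0.0159). The Shannon index was 3.76 ± 0.237 and 3.46 ± 0.297 (exact adjusted p = 0.349). Treatment accounted for an R2 of 0.629 of the Bray-Curtis distances (exact permutation test, p = 0.00794, adjusted p = 0.0159). The ampicillin mice also differed more among themselves, with a median Bray-Curtis distance of 0.688 against 0.258 in controls and an exact adjusted p of 0.0159 for the distances to the group centroid, so R2 mixes a shift with unequal spread. That spread lay between 2 sets of mice. Replicates 1 and 2 were 0.166 apart and replicates 3, 4 and 5 were 0.192 to 0.254 apart, while pairs across the sets were 0.688 to 0.766 apart. Of 306 variants tested, 188 changed, 29 higher and 159 lower. The largest fitted falls were in 2 variants of S24-7, from 3.95% ± 2.13 and 2.93% ± 2.19 of reads, and 1 of Mucispirillum schaedleri, all to no read. The largest fitted rises were in variants of Clostridiales without a family name (4.28% ± 3.96 of reads in ampicillin mice), Coprococcus (3.92% ± 1.07) and Clostridiales called to order only (2.45% ± 2.38), none with a read in controls. The Coprococcus variant was found in all 5 ampicillin mice, and the reads of the other variants lay almost wholly in replicates 3, 4 and 5. Of the variants of Oscillospira, 18 were lower and 1 higher, while the genus as a whole rose. Other Clostridiales taxa with a larger share also had more lower than higher variants. These were 19 and 8 in Clostridiales without a family name, and 11 and 6 in Lachnospiraceae without a genus name. Lachnospiraceae called to family only had 8 and 4, Coprococcus 5 and 2, and [Ruminococcus] gnavus 6 and 1. The Coprococcus variant above made up most of the 4.45% that its taxon took.

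**Figure D2:**
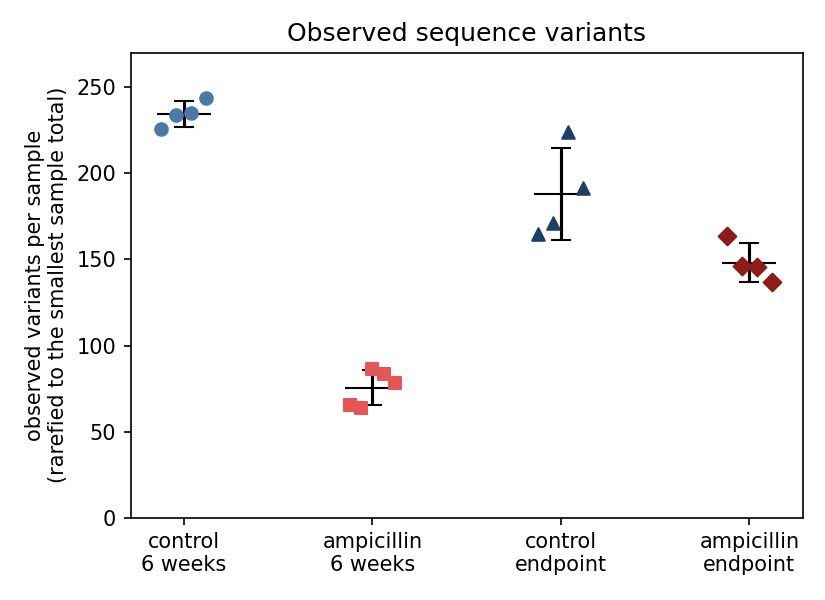
Each point is the number of sequence variants observed in 1 mouse at equal depth, averaged over 100 draws of 24034 reads, with the group mean and SD in black. The 5 ampicillin mice at 6 weeks lie between 63.7 and 86.5 and the 4 controls of that age between 226 and 244.

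The second comparison asked whether ampicillin mice still differed at the endpoint. Bacteroidetes made up 53.7% ± 6.72 of reads in controls and 2.84% ± 5.21 in ampicillin mice (0.236% without replicate 4, at 10.7%), and Firmicutes 40.3% ± 10.4 and 94.1% ± 5 (SD, n = 4 in each group). Both were at the smallest p that 4 mice against 4 can give, an exact permutation p of 0.0286, but the adjusted p over 7 phyla was 0.1, and 0 phyla passed by this test, on the log2 scale or on centred log ratios. Deferribacteres (1.69% ± 1.56 and 0.00144% ± 0.00287), Proteobacteria (1.43% ± 0.839 and 1.39% ± 0.691), Verrucomicrobia (2.50% ± 3.94 and 1.43% ± 1.18), Actinobacteria (0.327% ± 0.404 and 0.273% ± 0.0701) and Cyanobacteria (0.0224% ± 0.0247 and no read) did not pass either (exact adjusted p = 0.25 to 1). Of these means, Deferribacteres in controls was 1.11% and Actinobacteria 0.13% without replicate 2, Cyanobacteria 0.0106% without replicate 4 and Verrucomicrobia 0.534% without replicate 1. In ampicillin mice Verrucomicrobia was 0.894% without replicate 1, and Deferribacteres had reads in replicate 4 alone.

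Of 46 taxa, 25 changed at the endpoint, 11 higher and 14 lower in ampicillin mice. S24-7 stood at 35.1% ± 8.82 of reads in controls and 0.0332% ± 0.0554 in ampicillin mice (log2 fold change -10.01 ± 1.33 SE, adjusted p = 5.08e-05). Prevotella without a species name, at 5.95% ± 3.29, Bacteroides acidifaciens, at 2.63% ± 0.857, and Allobaculum, at 1.51% ± 2.58 of control reads, were at 0.00693%, 0.00238% and 0.0019% in ampicillin mice. S24-7 took 0.116% in ampicillin replicate 1 (mean 0.00553% without it), Prevotella 0.00416% without that mouse, and Bacteroides acidifaciens, Allobaculum, Rikenellaceae, Turicibacter and Sutterella had reads in that ampicillin mouse alone. Control replicate 3 held 5.37% Allobaculum and 3.48% Turicibacter, and the control means without it were 0.229% and 0.851%. Mucispirillum schaedleri was 1120-fold lower by pooled reads (exact 95% counting interval 309 to 9230, control mean 1.69% or 1.11% without replicate 2), Turicibacter 771-fold (264 to 3740), Rikenellaceae 579-fold (198 to 2810) and Sutterella 384-fold (106 to 3180). The groups overlapped in Mucispirillum schaedleri, since control replicate 3 had no read of it and ampicillin replicate 4 held 0.00575%. AF12 was at least 418-fold lower, Bacteroidales without a family name at least 134-fold, Desulfovibrio C21_c20 at least 87-fold (56-fold without control replicate 1) and Desulfovibrionaceae without a genus name at least 78.8-fold, the last call ending without control replicate 2 (4.87-fold, adjusted p = 0.0506) or with only the groups compared in the fit (adjusted p = 0.051). By limma on centred log ratios neither the last taxon (adjusted p = 0.203) nor Desulfovibrio C21_c20 (adjusted p = 0.0501) passed. Of the 9 Bacteroidales members tested, 6 were lower, 0 higher and 3 not past the threshold, among them Bacteroides without a species name (3.63% ± 4.75 and 2.51% ± 5, adjusted p = 0.863). [Prevotella] reached 3.61% ± 4.56 in controls, from replicates 1 and 2 alone, and was not tested under the read filter.

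Clostridiales called to order only rose from 0.775% ± 0.417 to 16.4% ± 9.39 of reads (4.40 ± 0.764 SE, adjusted p = 0.000183) and Lachnospiraceae without a genus name from 1.51% ± 1.01 to 12.1% ± 1.93 (3.00 ± 0.444 SE, adjusted p = 9.44e-05). [Ruminococcus] gnavus rose 6.02-fold to 5.23% ± 1.11, Lachnospiraceae called to family only 5.85-fold to 6.70% ± 2.82, Coprococcus 8.02-fold to 0.964% ± 0.212 and Clostridium methylpentosum 26-fold to 0.163% ± 0.0837. Butyricicoccus pullicaecorum, at 0.187% ± 0.182 in ampicillin mice, was at least 103-fold higher than in controls, which had no read, Staphylococcus at least 65.1-fold and Bifidobacterium pseudolongum at least 15.7-fold. These bounds were 57.4-fold without ampicillin replicate 2, 17.6-fold without replicate 4 and 7.91-fold without replicate 2. Control means moved to 0.516% for Lachnospiraceae called to family only without control replicate 3 (from 1.14%) and to 0.00382% for Clostridium methylpentosum without control replicate 4 (from 0.00626%). With TMMwsp factors the calls of [Ruminococcus] gnavus (adjusted p = 0.0967), Lachnospiraceae called to family only (0.0778) and Coprococcus (0.118) ended, that of Coprococcus also with only the groups compared in the fit (0.0766), and that of Bifidobacterium pseudolongum ended with DESeq2 (0.098). Clostridium colinum, at least 140-fold higher, lost its call without control replicate 1, 2 or 3 (adjusted p = 0.0505 to 0.0537) or ampicillin replicate 2 (15-fold, adjusted p = 0.085). Oscillospira took 7.73% ± 3.32 and 14.4% ± 2.65 of reads (0.90 ± 0.319 SE, adjusted p = 0.0229), but its fold change turned to -0.34 with TMMwsp factors (adjusted p = 0.544), and its call also ended with only the groups compared in the fit (0.0807) and without control replicate 1, 2 or 3 or ampicillin replicate 2 (adjusted p = 0.0544 to 0.0661). Clostridiales without a family name (22.7% ± 5.41 and 33.0% ± 6.26, adjusted p = 0.0764), Ruminococcus (0.995% ± 0.177 and 1.43% ± 0.369, adjusted p = 0.308), Bilophila (0.581% ± 0.342 and 1.39% ± 0.691, adjusted p = 0.175) and Akkermansia muciniphila, a mucin degrader (2.50% ± 3.94 and 1.43% ± 1.18, adjusted p = 0.583), did not pass. The median log2 fold change over the taxa tested was 0.00 on shares, -0.97 with TMMwsp factors, 0.29 with DESeq2 and 1.14 on centred log ratios, and the last 3 gave 7 higher and 15 lower, 17 and 13, and 19 and 12 calls.

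Among the fixed groups, 7 of 11 changed at the endpoint (exact adjusted p = 0.0449, two-sided permutation test, n = 4 in each group). The lists overlap as at 6 weeks, so this is not a count of separate changes. Bacteroidales held the same reads as Bacteroidetes in every mouse. The exact p of 0.0286 was the same for both, and only the adjustment differed (adjusted p = 0.1 over the 7 phyla). Lachnospiraceae made up 4.21% ± 1.87 of reads in controls and 25.4% ± 1.61 in ampicillin mice, Clostridiales 37.0% ± 9.61 and 92.2% ± 4.13, facultative anaerobe families 0.158% ± 0.171 (0.0736% without control replicate 3) and 1.79% ± 0.886, and the listed clostridial genera 1.44% ± 0.907 and 5.78% ± 1.13, of which [Ruminococcus] gnavus was 5.23%. In ampicillin mice the facultative anaerobes were mostly Lactobacillus without a species name (0.924%) and called to genus only (0.751%), with no read of Enterobacteriaceae. Erysipelotrichales, at 3.08% ± 3.96 (1.10% without control replicate 3) and 0.0303% ± 0.0098, Bacteroidales and Muribaculaceae were lower. Of the Erysipelotrichales sum in controls, 1.51% was Turicibacter, which the deposited taxonomy places outside that order. Ruminococcaceae (8.96% ± 3.22 and 17.2% ± 3.22, exact adjusted p = 0.0698), butyrate-producing genera (7.85% ± 3.31 and 15.6% ± 2.68, exact adjusted p = 0.0698), mucus-associated genera (10.5% ± 5.3 and 3.93% ± 4.26, or 1.85% without ampicillin replicate 4, exact adjusted p = 0.126) and Proteobacteria (exact adjusted p = 0.943) did not pass. Most of the butyrate-producing sum was again Oscillospira (7.73% in controls and 14.4% in ampicillin mice). When any 1 of the 8 mice except control replicate 4 was left out, 0 groups passed. All 7 stood at the smallest exact p of 0.0286, and fewer than 7 groups at that p cannot pass adjustment over 11. The groups thus pass or fail together, and this count cannot tell which of them depend on 1 mouse. Among members, 9 of 18 Clostridiales, 5 of 6 Lachnospiraceae, 3 of 6 Ruminococcaceae, 3 of 3 butyrate producers, 3 of 4 taxa of the listed clostridial genera and 1 of 4 facultative anaerobes were higher, with 0 lower. With TMMwsp factors these counts were 5, 2, 2, 1, 2 and 1, and with DESeq2 and by limma on centred log ratios 11, 5, 4, 3, 3 and 3. Of the mucus-associated taxa and of the Erysipelotrichales 2 of 4 were lower, and of the Proteobacteria 3 of 6 (1 by limma). Adjusted over the list alone, 1 of the 4 Erysipelotrichales was higher as well, which ended without any 1 of the 8 mice except control replicate 2, and the other 10 lists kept their counts. By that adjustment 0 facultative anaerobes were higher without any 1 control or without ampicillin replicate 4, and 1 Proteobacteria member was lower without control replicate 2.

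Observed variants numbered 188 ± 26.7 in controls and 148 ± 11.3 in ampicillin mice at the endpoint (exact permutation p = 0.0286, adjusted p = 0.0286). This call ended without control replicate 3 (difference -27.7, exact p = 0.0571) or without any 1 of the 4 ampicillin mice (exact p = 0.0571 to 0.114). Controls stayed above ampicillin mice in each case, though narrowly (at least 164.6 against at most 163.9). In groups of unequal size another relabelling can give as large a difference, so these losses do not show dependence on 1 mouse. The Shannon index was 3.77 ± 0.303 and 3.78 ± 0.175 (exact adjusted p = 0.971). Treatment gave an R2 of 0.682 of the Bray-Curtis distances (exact permutation p = 0.0286), and the distances to the centroid differed by -0.0332 (exact adjusted p = 0.486). Of 306 variants, 141 changed, 56 higher and 85 lower, and 37 of the lower ones belonged to S24-7. A variant of Clostridiales without a family name fell from 14.1% ± 3.38 of reads to 0.000951% ± 0.0019. The next largest fitted falls were in a variant of S24-7, from 2.24% ± 0.769, and of Bacteroides acidifaciens, from 1.07% ± 0.372, to no read. The largest fitted rises were in variants of Clostridiales without a family name (8.58% ± 6.03 of reads) and Lachnospiraceae (3.22% ± 1.73), none with a read in controls. A variant of Clostridiales called to order only passed on ampicillin replicate 3 alone, where it took 21.3% of reads (adjusted p = 1 without that mouse).

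The treatment comparisons at the 2 ages share no mouse, but their calls came from the same fit, with shared dispersions and the same read filter. Taxa and variants that are easier to call can then be on both lists more often than independence gives. The counts for independent lists below are therefore a reference only, and whether the overlap exceeds what the shared fit gives was not tested. Lower at both ages were 13 taxa, where lists of 23 and 14 among 46 would share 7 if they were independent, and higher at both were 7, against 2.39. The latter count was 0 with TMMwsp factors, 10 with DESeq2, 13 by limma on centred log ratios and 4 with only the groups compared in the fit or with reads outside Bacteroidetes as the total, a total chosen after seeing the data. The former was 13, 12, 9, 11 and 7. The 13 included S24-7, Rikenellaceae, Prevotella, Mucispirillum schaedleri and Sutterella, and the 7 included Coprococcus, [Ruminococcus] gnavus and both Lachnospiraceae taxa. Of sequence variants, 62 were lower at both ages against 44.2, and 11 higher at both against 5.31. Lower at 6 weeks and higher at the endpoint were 22, against 29.1, and the reverse 3, against 8.06.

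**Figure D3:**
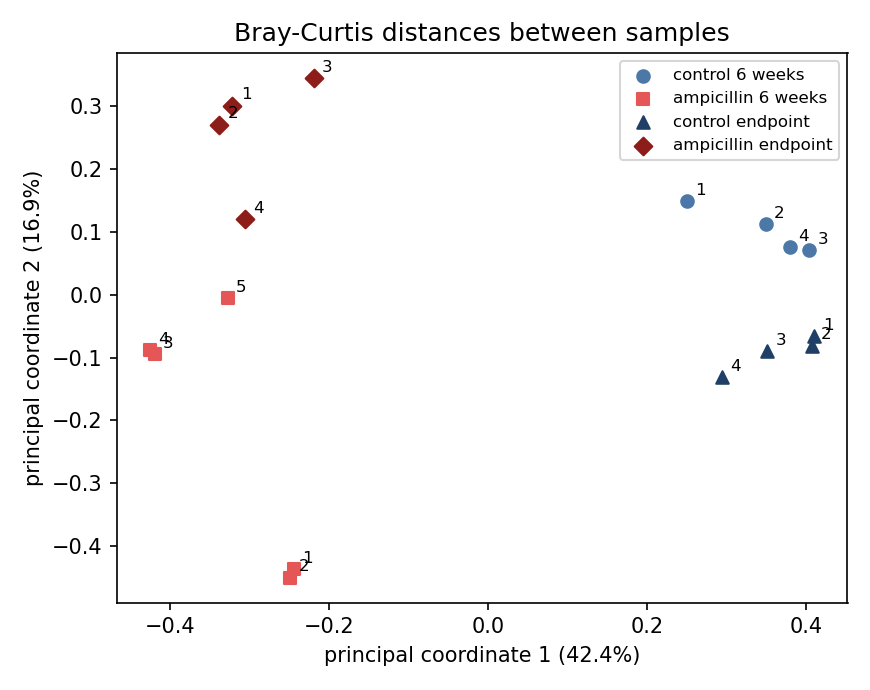
Principal coordinates of the Bray-Curtis distances between the 17 samples, with 42.4% and 16.9% of the positive eigenvalues on the horizontal and vertical axes and replicate numbers beside the points. The 9 ampicillin mice lie at -0.219 or below on the first coordinate and the 8 controls at 0.25 or above.

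The age comparisons asked how the community of untreated and of treated mice differed between 6 weeks and the endpoint. Each age was a separate set of mice, and batch and cage were not in the labels. A difference between ages, the interaction included, therefore cannot be told apart from one between these sets of mice. Words such as rose and fell compare the sets. In controls, 7 of 46 taxa differed between the endpoint and 6 weeks, 3 higher and 4 lower at the endpoint. Akkermansia muciniphila had no read at 6 weeks and took 2.50% ± 3.94 of reads at the endpoint, at least 1610-fold higher (adjusted p = 0.00134), and Turicibacter was at least 968-fold higher (adjusted p = 0.00399). Control replicate 1 of the endpoint held 8.41% of Akkermansia muciniphila, and without it the mean was 0.534% and the bound 343-fold. Without endpoint replicate 3 the bound of Turicibacter was 546-fold. Clostridiales without a family name rose from 7.62% ± 1.54 to 22.7% ± 5.41 (1.57 ± 0.254 SE, adjusted p = 0.000274). Clostridiales called to order only fell from 31.3% ± 6.82 to 0.775% ± 0.417 (-5.34 ± 0.799 SE, adjusted p = 0.000217), Butyricicoccus pullicaecorum was at least 138-fold lower, and Clostridium methylpentosum fell from 0.303% ± 0.105 to 0.00626% ± 0.00727 (0.00382% without endpoint replicate 4). Lachnospiraceae without a genus name fell from 4.08% ± 0.938 to 1.51% ± 1.01 (adjusted p = 0.0234), a call that ended without 6-week replicate 1 or 4 or endpoint replicate 2 (adjusted p = 0.0666 to 0.07), with TMMwsp factors (0.0867), DESeq2 (0.0941), limma on centred log ratios (0.0608) or only the groups compared in the fit (0.105). The order-only fall rested largely on a single variant, which took 26.2% ± 6.51 of reads at 6 weeks and had no read at the endpoint, whereas a variant of Clostridiales without a family name went from no read to 14.1% ± 3.38. A Lachnospiraceae variant, at 0.799% ± 0.195 of reads, and another order-only variant, at 3.21% ± 1.09, also fell to no read, the latter call ending without any 1 of the 4 endpoint mice (adjusted p = 0.0508 to 0.0604). Counts of higher and lower taxa were 4 and 3 with DESeq2 and 6 and 4 by limma on centred log ratios, and the median log2 fold change was -0.15 on shares, -0.17 with TMMwsp factors, 0.04 with DESeq2 and 0.08 on centred log ratios. S24-7 (adjusted p = 0.845), Oscillospira (adjusted p = 0.105), Prevotella without a species name (adjusted p = 0.197), Rikenellaceae (adjusted p = 0.212), Mucispirillum schaedleri (adjusted p = 0.696), AF12 (adjusted p = 0.845), Sutterella and Allobaculum (adjusted p = 0.37) did not pass, nor did Bacteroides (adjusted p = 0.836), Bacteroides acidifaciens (adjusted p = 0.567), Lachnospiraceae called to family only (adjusted p = 0.197) and Ruminococcus (adjusted p = 0.945).

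Between the 2 control ages 63 of 306 variants changed, 14 higher and 49 lower. Observed variants were lower at the endpoint (235 ± 7.47 and 188 ± 26.7, exact permutation p = 0.0286), a call that ended without any 1 of the 4 mice of 6 weeks (exact p = 0.0571). The ages stayed apart in each case, though narrowly (at least 225.6 at 6 weeks and at most 224.2 at the endpoint). This loss, too, does not show dependence on 1 mouse, since groups of unequal size allow another relabelling as large a difference. The Shannon index did not pass (exact adjusted p = 0.971), and R2 was 0.588 (exact permutation p = 0.0286). Of the 11 fixed groups, 0 passed the exact permutation test with adjustment, on the log2 scale or on centred log ratios. Erysipelotrichales and butyrate-producing genera stood at an unadjusted exact p of 0.0286 and were higher by 2.85 and 2.78 percentage points, which fell to 0.868 without endpoint replicate 3 and to 1.14 without endpoint replicate 4. Members past the threshold were 1 higher and 4 lower of 18 Clostridiales, 2 lower of 6 Ruminococcaceae, and 0 of 9 Bacteroidales (2 higher by limma on centred log ratios) and of 6 Proteobacteria. Adjusted over the list alone, 1 Ruminococcaceae member, 1 butyrate producer and 1 listed clostridial member were higher in addition, and each of these ended without any 1 of at least 3 of the 4 mice of 6 weeks.

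In ampicillin mice, 16 of 46 taxa differed between the endpoint and 6 weeks, 14 higher and 2 lower at the endpoint, and the split was 11 and 3 with DESeq2 and 8 and 11 by limma on centred log ratios, where the median log2 fold change was -0.80 against 1.53 on shares and 1.28 with TMMwsp factors and with DESeq2. Akkermansia muciniphila was at least 1390-fold higher (1.43% ± 1.18 of reads at the endpoint), Bilophila at least 1350-fold (1.39% ± 0.691), Lactobacillus without a species name at least 903-fold (0.924% ± 0.693), Adlercreutzia at least 239-fold (0.245% ± 0.0812) and Butyricicoccus pullicaecorum at least 183-fold, all from no read at 6 weeks. Without endpoint replicate 1 the bound of Akkermansia muciniphila was 873-fold, and without replicate 2 that of Butyricicoccus pullicaecorum 102-fold. Parabacteroides distasonis rose from no read to 0.129% ± 0.144 (0.0587% without endpoint replicate 1), and Bifidobacterium pseudolongum, Mogibacteriaceae without a genus name, Coprobacillus and Ruminococcaceae called to family only were at least 27.8-fold, 24.9-fold, 22.9-fold and 11.2-fold higher. Without endpoint replicate 2 the bounds of Bifidobacterium and Ruminococcaceae were 14-fold and 5.5-fold, and without replicate 4 that of Mogibacteriaceae 10.8-fold. On centred log ratios by limma, Bifidobacterium pseudolongum (adjusted p = 0.0909, and 0.154 with DESeq2) and Ruminococcaceae called to family only (0.356, and 0.0526 with only the groups compared in the fit) did not pass. Parabacteroides called to genus only and Mogibacteriaceae called to family only passed on reads of endpoint replicate 4 alone, and without that mouse no read of either remained (adjusted p = 1). Clostridium methylpentosum fell from 1.49% ± 0.204 to 0.163% ± 0.0837 (-3.19 ± 0.95 SE, adjusted p = 0.0149). Enterobacteriaceae, at least 27.5-fold lower (7.85-fold without 6-week replicate 4), lost its call without endpoint replicate 1 (adjusted p = 0.0528). S24-7 (adjusted p = 0.0749), Coprococcus and [Ruminococcus] gnavus (adjusted p = 0.0708), Clostridiales without a family name and Lachnospiraceae without a genus name (adjusted p = 0.157 each), Clostridiales called to order only (adjusted p = 0.735), Lachnospiraceae called to family only (adjusted p = 0.342), Oscillospira (adjusted p = 0.859), Bacteroides (adjusted p = 0.681) and Ruminococcus (adjusted p = 0.422) did not pass.

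Observed variants rose between the ages of ampicillin mice, from 75.5 ± 10.3 to 148 ± 11.3 (exact permutation p = 0.00794, adjusted p = 0.0159), the Shannon index did not pass (exact adjusted p = 0.349), and R2 was 0.442 (exact permutation test, adjusted p = 0.0159). Of 306 variants, 135 changed, 97 higher and 38 lower. The largest fitted rises were in variants of Lachnospiraceae (3.22% ± 1.73 of endpoint reads), Clostridiales called to order only (3.22% ± 0.752) and Clostridiales without a family name (2.58% ± 2), and the largest falls in a variant of Coprococcus (from 3.92% ± 1.07) and 2 of Lachnospiraceae called to family only (from 1.34% ± 1.84 and 1.24% ± 1.69). The latter 2 had their reads in ampicillin replicates 1 and 2 at 6 weeks, save 0.00461% in replicate 3 for the second, and the call of the first ended without any 1 of the 4 endpoint mice (adjusted p = 0.0583 to 0.0668). Facultative anaerobe families (1.79% ± 0.886 at the endpoint) and Proteobacteria (1.39% ± 0.691) were the 2 of 11 groups that rose (exact adjusted p = 0.0437). The facultative anaerobes were mostly Lactobacillus without a species name (0.924%) and called to genus only (0.751%), with no endpoint read of Enterobacteriaceae. The Proteobacteria were almost wholly Bilophila (1.39%). On the log2 scale, on centred log ratios or when any 1 of the 9 mice was left out, 0 groups passed. Members past the threshold were 4 higher of 9 Bacteroidales, 4 higher and 1 lower of 18 Clostridiales, and 1 higher and 1 lower of 6 Proteobacteria. On centred log ratios by limma 1 was higher and 2 lower of the Bacteroidales, and 2 and 7 of the Clostridiales, and with DESeq2 2 Bacteroidales were higher. Of the 4 Bacteroidales, Bacteroides acidifaciens had 5 reads, in endpoint replicate 1 alone, Parabacteroides called to genus only 224, in replicate 4 alone, and Prevotella 11, in replicates 1 and 2, while Parabacteroides distasonis had reads in all 4 mice. Adjusted over the list alone, 6 Bacteroidales were higher, among them S24-7 and Rikenellaceae, but 4 without any 1 mouse of 6 weeks and 3 without endpoint replicate 1. S24-7, the 1 member of the Muribaculaceae list, was higher there too, which ended without that mouse or 6-week replicate 1 or 5, and 1 butyrate producer was lower, which ended without any 1 of the 9 mice. Endpoint replicate 1 held all 3 reads of Rikenellaceae and 0.116% of S24-7, which stood at 0.00832% or less in the others. It also held 21 of 75 control-type variants at up to 12 reads each, against 1 or 2 in the other ampicillin mice.

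The difference between treatments was not the same at the 2 ages in 15 of 46 taxa. The log2 fold change, ampicillin over control, was more positive at the endpoint in 13 and more negative in 2. By limma on centred log ratios the split was 6 and 6. The 5 smallest adjusted p were those of Bilophila (1.4e-05), Clostridiales called to order only (0.000497), Butyricicoccus pullicaecorum and Adlercreutzia (0.000641 each) and Turicibacter (0.00269). Bilophila, Adlercreutzia and Butyricicoccus pullicaecorum had no read in ampicillin mice at 6 weeks and took 1.39%, 0.245% and 0.187% at the endpoint. Controls differed as well. These taxa took 0.916%, 0.239% and 0.25% of control reads at 6 weeks, and 0.581%, 0.0835% and no read at the endpoint. Clostridiales called to order only differed mostly in controls, at 31.3% and 0.775%, against 12.8% and 16.4% in ampicillin mice. Turicibacter had reads in ampicillin mice and none in controls at 6 weeks, and took 1.51% ± 1.32 of control reads and 0.00143% ± 0.00285 of ampicillin reads at the endpoint. Of the 15 calls, 5 rested on reads of 1 mouse and had an adjusted p of 1 without it: Rikenellaceae and Sutterella (endpoint ampicillin replicate 1, with 3 and 2 reads), Mogibacteriaceae called to family only (endpoint ampicillin replicate 4), Bifidobacterium pseudolongum (6-week control replicate 2) and Parabacteroides distasonis (6-week control replicate 3). Those of Clostridiales without a family name (adjusted p = 0.126 with TMMwsp factors and 0.0606 with DESeq2) and, by limma on centred log ratios, of Mogibacteriaceae without a genus name (0.433) and Ruminococcaceae called to family only (0.26) ended too. With the replicate block these 3, the 5 and Lactobacillus ended (adjusted p = 0.0595 to 0.139). All these were named after their values were seen. The interaction was past the threshold in 77 of 306 variants, 68 and 9. For observed variants it was 119 (permutation p = 0.00013 over 100000 draws), and for the Shannon index 0.306 (permutation p = 0.248).

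**Figure D4:**
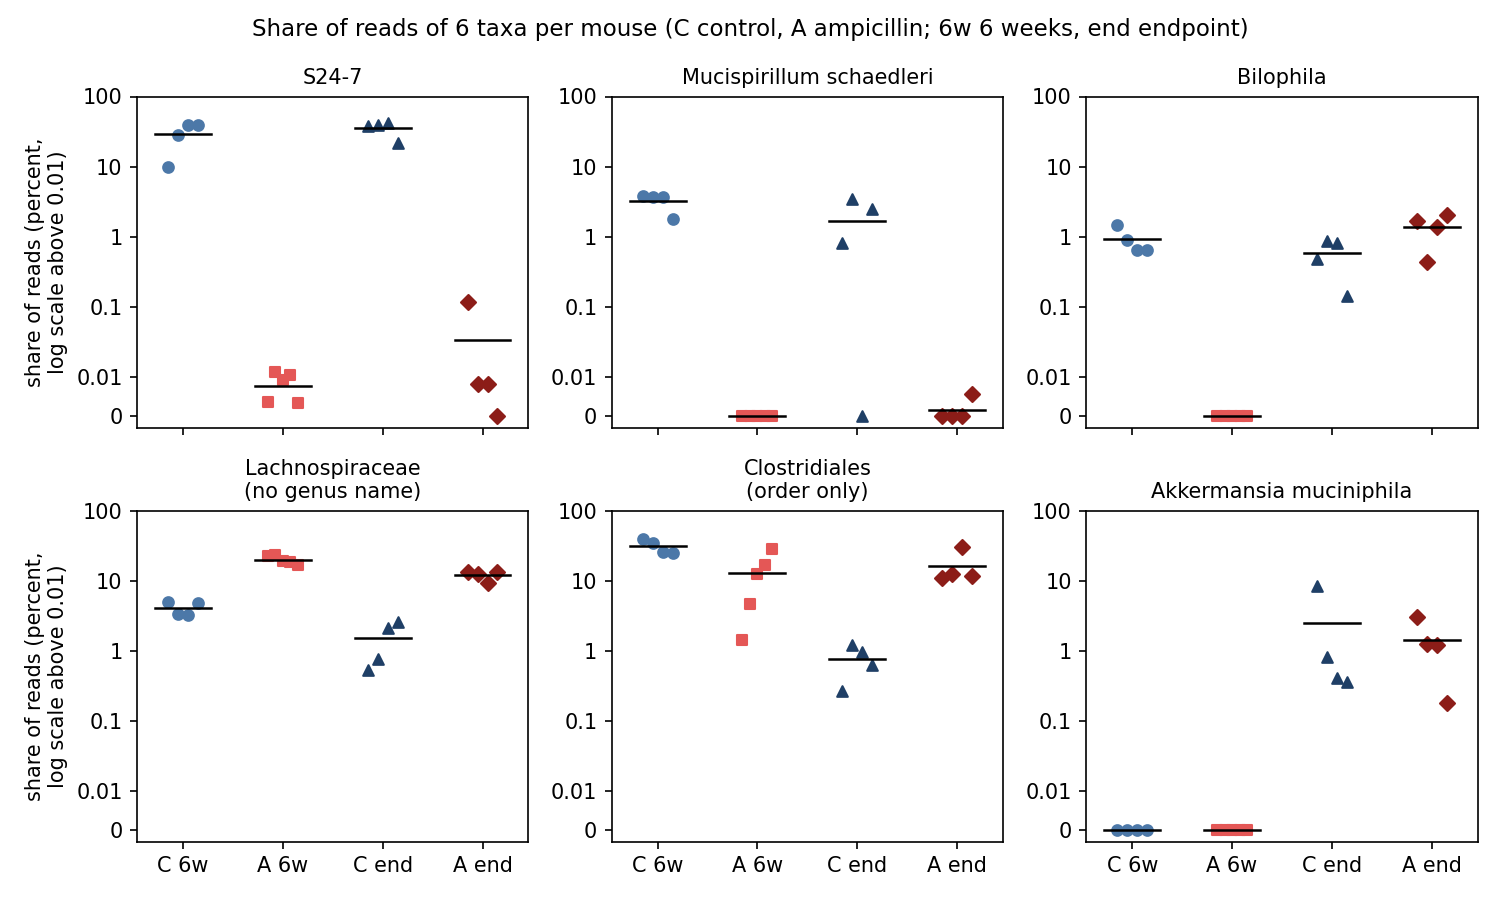
Points give the share of reads in percent of 6 taxa in each mouse, on a vertical scale that is linear up to 0.01% and logarithmic above, with the group mean as a line. Bilophila and Akkermansia muciniphila have no read in the 5 ampicillin mice at 6 weeks and reads in all 4 ampicillin mice at the endpoint, while S24-7 stays at or below 0.116% in the ampicillin mice of both ages.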

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

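The tests of the trace variants below were chosen after their counts were seen. Of 175 groups of mice checked for a single distant sample, 39 were marked, where chance marks about 1 in 20 groups, or 8.75. Many of these shares are near 0 or overlap, since a taxon and its phylum can hold the same reads.

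In controls at 6 weeks, the distant values were Deferribacteres at 1.81% (low), Erysipelotrichales and Allobaculum at 0.712% in replicate 4, Bacteroides at 3.40% in replicate 1, Bifidobacterium pseudolongum at 0.00795% in replicate 2 and Parabacteroides distasonis at 0.00528% in replicate 3. In ampicillin mice of that age, replicate 4 had the highest Proteobacteria (0.220%) and Enterobacteriaceae (0.216%), replicate 3 the highest Staphylococcus (0.113%) and replicate 1 the highest Turicibacter (0.0801%). In endpoint controls, replicate 4 stood apart in Ruminococcaceae (13.7%), butyrate-producing genera (12.8%), Oscillospira (12.7%) and Bacteroides (10.7%). Replicate 3 stood apart in Erysipelotrichales (9.01%), Allobaculum (5.37%), Turicibacter (3.48%) and Lactobacillus (0.298%), replicate 1 in Verrucomicrobia (8.41%), and replicate 2 in Desulfovibrionaceae (0.611%) and Coprobacillus (0.00779%). In endpoint ampicillin mice, replicate 4 had 10.7% Bacteroidetes, all of it Bacteroidales, and 10% Bacteroides, and also the highest Parabacteroides (0.644%), Staphylococcus (0.376%), both Mogibacteriaceae taxa (0.0690% and 0.0661%) and Deferribacteres (0.00575%). Replicate 3 had 9.24% Lachnospiraceae without a genus name (low), 30.4% Clostridiales called to order only and 0.00552% [Prevotella], and replicate 2 had 0.932% Clostridium colinum.

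Endpoint ampicillin replicate 1 had the highest share in its group of Muribaculaceae (0.116%), Bacteroides acidifaciens (0.00951%), Allobaculum (0.00761%), Rikenellaceae and Turicibacter (0.00571% each) and Sutterella (0.0038%). Of 75 variants with at least 200 reads over the controls and at most 12 in each ampicillin sample, this sample held 21 with 84 reads, while the other ampicillin samples held 1 or 2 each. Thinning to 24034 reads left 17.9 on average, which argues against depth. Carry-over from control samples may account for it, but at a fixed ratio the best-matching control sample gave a simulated p of 0.023, and over 12 settings of read limits and pseudo-count the best p ran from 0.0024 to 0.07, with 1 setting at 0.05 or more. Carry-over and a few returning or surviving bacteria cannot be told apart with these counts.

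The treatment difference was not the same at the 2 ages in observed variants (119) and in 15 taxa by the edgeR interaction test. Their adjusted p were 1.4e-05 (Bilophila), 0.000497 (Clostridiales called to order only), 0.000641 (Butyricicoccus pullicaecorum and Adlercreutzia), 0.00269 (Turicibacter), 0.00688 (Coprobacillus), 0.0148 (Ruminococcaceae called to family only and Lactobacillus), 0.0194 and 0.026 (Mogibacteriaceae without a genus name and called to family only), 0.021 (Clostridiales without a family name), 0.0263 (Rikenellaceae), 0.0298 (Bifidobacterium pseudolongum), 0.0338 (Parabacteroides distasonis) and 0.045 (Sutterella). Those of Rikenellaceae and Sutterella rested on 3 and 2 reads in endpoint ampicillin replicate 1, the sample for which carry-over is left open above, and that of Mogibacteriaceae called to family only on endpoint ampicillin replicate 4. Those of Bifidobacterium pseudolongum and Parabacteroides distasonis rested on 6-week control replicates 2 and 3, and without the mouse in question each of the 5 had an adjusted p of 1. Those of Sutterella and Parabacteroides distasonis also ended without other single mice (adjusted p = 0.0502 to 0.0794). That of Clostridiales without a family name ended with TMMwsp factors (0.126) and DESeq2 (0.0606), and those of Mogibacteriaceae without a genus name (0.433) and Ruminococcaceae called to family only (0.26) by limma on centred log ratios. With the replicate block 9 of the 15 ended (0.0595 to 0.139).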

How the results depend on the processing

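The 2 other library totals were chosen after seeing the data. In the alternatives other than those given here, counts of changed taxa and variants stayed within 1.5 times and the diversity tests kept their direction and side of the threshold. With reads of Clostridiales as the total, 9 taxa changed at 6 weeks, 7 at the endpoint, 8 between ages of ampicillin mice and 7 in the interaction, a total under which only Clostridiales are tested. With the filter of 50 reads in 4 samples, where fewer taxa are tested, 9 changed between ages of ampicillin mice and 8 in the interaction. For ampicillin mice between ages, 0 taxon groups passed on the log2 scale and 0 on centred log ratios; the cause was not tested. Oscillospira at the endpoint turned to -0.34 with TMMwsp factors, -0.13 with reads outside Bacteroidetes and -0.39 with reads of Clostridiales as the total. Clostridiales without a family name at the endpoint turned from 0.54 to -0.52 with reads outside Bacteroidetes as the total, and was then lower (adjusted p = 0.00984). The inverse Simpson index differed by 8.90 at 6 weeks, opposite in sign to the Shannon index, and neither passed.

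Replicate numbers did not pair the mice: correlations of same-numbered deviations ran from -0.119 to 0.168, and not every mouse matched its own number best. With the replicate block, 8 taxa changed between ages of ampicillin mice and 6 in the interaction, and 118, 87, 16, 61 and 51 variants in the 5 comparisons. With 4 pairs the exact p cannot go below 0.125, so the blocked differences of observed variants (-159.8, -39.8, -46.7 and 73.3), the blocked R2 (0.669, 0.682, 0.588 and 0.473) and the blocked group and phylum counts (0) could not pass.

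Leaving out 1 mouse at a time moved the difference in observed variants from -47.5 to -27.7 at the endpoint and from -58.8 to -39.0 between control ages, and the Shannon difference from -0.0966 to 0.146 and from -0.124 to 0.119. Taxon groups changed numbered 0 to 7 at the endpoint, where at least 7 groups must stand at the smallest p for any to pass. They numbered 0 between ages of ampicillin mice, where fewer mice raise the smallest p. Of the named taxa past the threshold, 10 of 22 kept call and direction in every alternative at 6 weeks, 15 of 23 at the endpoint, 6 of 7 between control ages, 8 of 14 between ages of ampicillin mice and 5 of 5 in the interaction. Of the named variants 5 of 6, 4 of 6, 4 of 6 and 4 of 6 did so in the first 4 comparisons. These have no value among the operational taxonomic units. Depth limits taxa below about 0.0125% in the smallest sample.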

Other observations

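The tests in this part were chosen after the result was seen, except that of depth differences below. Of the 23 taxa lower in ampicillin mice at 6 weeks, 13 were lower at the endpoint as well, 1, Butyricicoccus pullicaecorum, was higher, and 9 were not past the threshold. Bilophila, Lactobacillus without a species name, Adlercreutzia, Coprobacillus and Mogibacteriaceae without a genus name went from no read in the 5 mice of 6 weeks to 2202, 1335, 375, 35 and 36 reads, spread over all 4 endpoint mice. Of the 23, AF12, Desulfovibrio C21_c20, F16, YS2, Desulfovibrionaceae, RF32 and Bacteroidales without a family name had no read in ampicillin mice of either age.

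The higher share of Clostridiales after ampicillin may follow from the loss of Bacteroidetes reads from a fixed total. Among reads outside Bacteroidetes the order took 88.4% ± 1.57 in controls and 99.7% ± 0.276 in ampicillin mice at 6 weeks, and 79.1% ± 9.81 and 95% ± 1.47 at the endpoint, so that the log2 ratio of its mean shares went from 0.78 to 0.17 and from 1.32 to 0.26. Most of the rise of the order as a whole thus goes with the lower share of Bacteroidetes, but controls left room for a ratio of only 0.18 and 0.34, so this cannot decide whether the loss is the cause. As the sole cause the loss would give each taxon outside Bacteroidetes a log2 rise of about 0.61 at 6 weeks and 1.07 at the endpoint, but 5 of the 6 Clostridiales taxa with at least 1% of control reads differed from that at 6 weeks, 4 above and 1 below, and 3 of 4 at the endpoint, 2 above and 1 below, which argues against it as the sole cause of their changes. With TMMwsp factors, which assume that most taxa keep their level, 0 of the 7 taxa higher at 6 weeks passed, and whether there were more such cells per cecum cannot be told, because load was not measured.

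Mice with neighbouring sample numbers may resemble each other, for instance through a shared cage or order of handling. This was noticed in ampicillin mice at 6 weeks, where Bacteroides took 19.8% and 17.4% of reads in replicates 1 and 2 and at most 0.00922% in the others. Over the 28 pairs within groups, distance rose with the gap in sample number (permutation p = 0.0097, correlations of 0.81 and 0.68 in controls and ampicillin mice at 6 weeks and 0.31 and -0.07 at the endpoint), but without the group in which it was noticed the permutation p was 0.1, which leaves it open. Distance did not rise with the difference in depth (permutation p = 0.85), which argues against depth. Cages were not in the labels, and no biological explanation was tested.

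Other splits of the same mice were counted to see whether chance can be excluded. At 6 weeks 1 of 100 splits, the real one, gave as many taxa (33, highest other 30), at the endpoint 1 of 35 (25, highest other 2), between control ages 1 of 35 (7, highest other 1) and between ages of ampicillin mice 1 of 100 (16, highest other 13). For variants the counts were 1 of 100 (188, highest other 172), 1 of 35 (141, highest other 0), 1 of 35 (63, highest other 0) and 1 of 100 (135, highest other 100). For the interaction 4 of 100 splits gave as many taxa (15, highest other 17) and 2 of 100 as many variants (77, highest other 80). All these shares lie under 0.05. For the treatment and age comparisons chance can thus be excluded at that level, for mice that are independent. For the interaction some other splits gave more calls than the real one, so chance is not excluded there. The splits do not cover a shared cage, which stays open above, and shares would be too small if mice of a group shared cages.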
